A study of Oryza sativa Japonica Group with 24 samples.

How the data were processed

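RNA was measured in roots of 2 rice cultivars, Nipponbare and IAC165, after inoculation of 21-day-old seedlings with 25 mg of germinated seeds of Striga hermonthica, a parasitic plant that attaches to host roots, or after mock inoculation. Roots were taken 2, 4 and 11 days later, with 2 biological replicates in each of the 12 groups and 1 array per replicate. Per the labels, total RNA was labelled with biotin by the Affymetrix 3' in vitro transcription protocol and processed with GCOS, the vendor's array software. The version and settings of GCOS are not given in the sources used here.

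The deposited values are signal intensity per probe set on a linear scale, for 57381 probe sets on 24 arrays, of which 123 are controls. The mean signal without the highest and lowest 2% of probe sets was 100.012 to 100.014 on each array, so the authors' values had been scaled to a common mean on each array. Calls of presence and scan dates were not used here, and the number of arrays limits the precision.

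Signals were put on the log2 scale after 96 zeros were set to the lowest signal, 0.1. Probe sets were tested when their second-highest signal exceeded the pooled median of 20.5, which left 38694. The plan written before the data were examined was to centre each array on its median if the medians differed by more than 0.2 on the log2 scale. The medians over all rice probe sets, 15.9 to 27.2, differed by 0.77, but they lie at the level of dim probe sets. Over the 20031 probe sets above 20.5 on all arrays the medians were 171.5 to 180.4 and differed by 0.073, and no centring was applied. That reading of the plan was made before any test, and centring on either median was added as an alternative after seeing the data. Centring on all probe sets shifted the mean infection effect by 0.32 in Nipponbare and 0.29 in IAC165 on the log2 scale, by up to 0.50 on a single day, and the cultivar difference in mock roots by -0.12.

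A linear model with 12 group means was fitted in limma 3.58.1 (R 4.3.3, statmod 1.5.0), with 12 residual degrees of freedom, an intensity trend in the prior variance and 6.11 prior degrees of freedom. Contrasts were infected minus mock roots in each cultivar on each day and averaged over the 3 days, the difference of these effects between cultivars (Nipponbare minus IAC165), their change from day 2 to day 11, and Nipponbare minus IAC165 in mock roots. Tests were two-sided. P-values were adjusted by the Benjamini-Hochberg method over the probe sets tested in each contrast, and a probe set was called at an adjusted p below 0.05. On simulated data with 200 changed probe sets, the model found 21% of 2-fold and 51% of 4-fold changes in a 1-day contrast, and 45% and 79% in the mean effect of IAC165. For the cultivar difference in the mean effect it found 50% and 66%. Of the calls, 6.49%, 6.06% and 3.33% were false in these contrasts, in this order. The adjusted threshold depends on how many probe sets change. These shares therefore do not carry over to contrasts with many more calls, such as the 7097 of the mean effect in IAC165.

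Probe sets were joined to genes through the platform annotation. Exactly 1 gene was listed for 22436 probe sets, several genes for 95 and none for 34850, and 3188 probe sets had a gene with a name. Probe sets whose names end in _s_at or _x_at can bind transcripts of related genes. Among the genes named below, those that rest on such probe sets include OsChia1c, OsABCG44, KIN13B, OsMT-2, OsPP2C12, GST1 and LOGL1. The same holds for OsNSHB1 in IAC165 and for the second probe sets of OsNSHB1 and OsCHS1. The 32 gene lists were fixed before the data were examined and were translated into gene symbols after the annotation was seen and before any test. Of the 31 lists with members, 28 had at least 3 genes and were tested, with 601 memberships of 583 genes. Only genes with a name could join a list, 2453 of the 17905 genes with a probe set. A list therefore need not cover its gene family, and its counts hold for its named members alone. A gene was represented by its probe set of highest mean signal. Lists were tested against all other probe sets with camera at a preset correlation of 0.01, and again with an estimated correlation, and adjusted over the lists of a contrast. Fry was run as an alternative. List members are the brightest probe sets of named genes, while the other probe sets include many dim ones. The median mean infection effect in Nipponbare was 0.051 over all probe sets tested and -0.032 over the brighter ones. In IAC165 it was 0.088 and 0.003. A list of bright probe sets can therefore lean slightly down in camera, and lists were not matched for signal.

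Genes named in the text were chosen by a rule fixed before the data were examined. Among called probe sets with 1 named gene, the rule took the 8 highest and 8 lowest log2 fold changes of each mean effect, 5 and 5 for each 1-day effect, for the cultivar difference in the mean and for mock roots, and 3 and 3 for the other contrasts. It added the member with the smallest p in each direction of each list. A gene named for a mean effect had the same sign on each of the 3 days, and a gene named for a 1-day effect had both infected arrays outside the range of both mock arrays. Some genes the rule took were left out of the text. Where both arrays of every group on the dimmer side lay below 20.5, the fold was computed against 20.5 and is given as a lower bound. Other log2 changes that rest in part on signals below 20.5 are also given floored, with each signal below 20.5 set to 20.5. These values were added after seeing the data, and the SE and p-values belong to the values as fitted. Values after ± are SE for log2 changes and SD for signals. No coordinates are given, since no genome build was named.

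Alternatives were quantile normalization, an offset of 4.9 before the logarithm, no filter (57258 probe sets), a stricter filter at a signal of 100.2 (17774 probe sets), no intensity trend, array weights, a 2-fold threshold, a model of the compared groups alone, a replicate block, and leaving out each array in turn. Leaving out an array leaves its group with 1 array, which is assumed to vary like the other groups. Deviations of same-numbered infected and mock arrays from their group means, over the brighter probe sets, had correlations from -0.29 to 0.13. Both extremes were at day 11, the lowest in Nipponbare and the highest in IAC165. Replicate numbers were therefore not taken to pair infected with mock arrays, and the main model had no block. These values do not exclude a pairing at day 11. Added after seeing the data were both centrings, the mean over days 2 and 4 alone, and a block with crossed replicate numbers. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.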

Results

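Expression was measured with 24 rice arrays in roots of Nipponbare and IAC165, 12 arrays per cultivar. From what is known of these cultivars, Nipponbare is resistant and IAC165 susceptible to Striga hermonthica, and the study set the resistant beside the susceptible interaction. Each combination of cultivar, treatment (infected or mock) and day (2, 4 or 11 days after inoculation) had 2 arrays. The 75th percentile of the signal lay between 96.0 and 105.8 on the 24 arrays. The correlation of log2 signals between replicates, across the 20031 brighter probe sets, ran from 0.949 in infected Nipponbare roots at day 11 to 0.987 in mock Nipponbare roots at day 2. The ratio of 3' to 5' signal of GAPDH, a sign of RNA quality, was 3.66 to 6.17 in mock and 3.96 to 6.29 in infected roots.

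The arrays separated by cultivar along the component with the largest variance and by infection along the next. Component 1 held 26.6% of the variance. Along component 2, with 23.1%, mock arrays of IAC165 lay between -25.4 and -2.15 and infected ones between 14.0 and 51.1. Mock arrays of Nipponbare lay between -37.8 and -11.8 and infected ones between -15.1 and 40.9, so that these ranges overlapped.

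**Figure D1:**
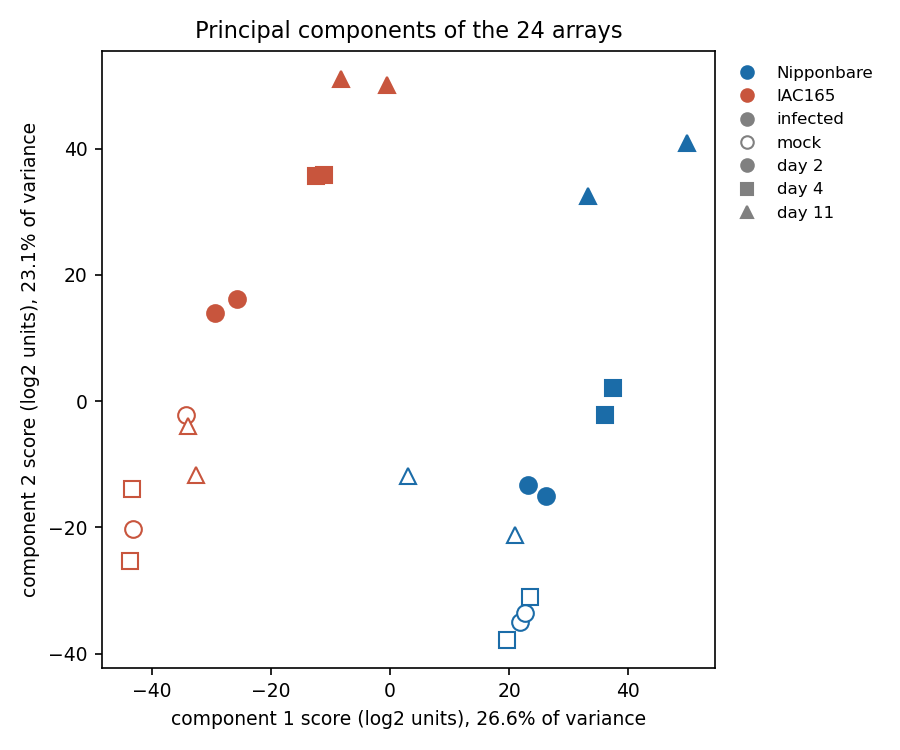
Each point is 1 of 24 arrays, placed by its scores on components 1 and 2 (log2 units); colour gives the cultivar, filled or open the treatment and shape the day. Component 1 separates the cultivars, and on component 2 the infected arrays of each cultivar and day lie above the mock arrays of that cultivar and day.

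The mean infection effect in Nipponbare asks which genes respond to the parasite in the resistant cultivar. Signal from RNA of the parasite was not separated from that of rice, so a rise in infected roots, here and below, can include it. The chitinase gene OsChia1a, whose family degrades chitin, had a signal of 2284 ± 1407 in 6 infected arrays and 243 ± 119 in 6 mock arrays, a rise of 3.14 ± 0.20 on the log2 scale (adjusted p = 1.5e-08). Cht11, another chitinase gene, rose by 3.38 ± 0.26 (adjusted p = 1.2e-07), or by 2.94 when floored, that is with each signal below 20.5 set to 20.5. OsNIP1;1, an aquaporin of the nodulin-like family, rose by 3.62 ± 0.20 (adjusted p = 3.3e-09), or by 3.61 when floored. PBZ1, a probenazole-induced pathogenesis-related protein of the PR10 family, rose by 2.98 ± 0.44 (adjusted p = 2.6e-04). Among the genes that fell were OsSWEET1a, a sugar transporter, by 1.14 on the log2 scale, and OsZIP4, a zinc transporter, by 1.00.

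Enzymes of the diterpenoid phytoalexins, the antimicrobial terpenes of rice, rose together in Nipponbare. Of 15 members tested, 10 rose and 0 fell (12 rose when adjusted over the list alone; camera adjusted p = 3.2e-10, and adjusted p = 0.036 with an estimated correlation). They included the cyclase gene OsDTS2, which rose by 3.16 (1.62 when floored), and the cytochrome P450 genes CYP99A3, by 2.12, and CYP99A2, by 3.12 (2.55 when floored). The call of CYP99A2 was lost in 3 of the 12 runs that left out 1 array, with adjusted p up to 0.0621. Of 11 chitinases and glucanases 6 rose (6 adjusted over the list alone; adjusted p = 1.7e-06, and adjusted p = 0.036 with an estimated correlation).

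Of 34 jasmonate genes, which make or answer this defence hormone, 13 rose (19 rose and 2 fell adjusted over the list alone; adjusted p = 1.1e-07, and adjusted p = 0.036 with an estimated correlation). OsJAZ11, a repressor of jasmonate responses, rose by 2.96 (1.48 when floored), and OsOPR4, of the oxophytodienoate reductases, by 1.31. Of 10 PDR and ABCG transporters 5 rose and 2 fell, also 5 and 2 when adjusted over the list alone. By camera the list had adjusted p = 0.0049, and adjusted p = 0.044 with an estimated correlation. OsABCG44 rose by 2.480 (2.475 when floored). Of 6 WRKY transcription factors 4 rose and 1 fell (4 and 1 adjusted over the list alone; adjusted p = 0.0022, but adjusted p = 0.063 with an estimated correlation), led by OsWRKY76 at 2.04 ± 0.18. Of 27 cytochrome P450 genes 9 rose and 1 fell (11 and 5 adjusted over the list alone; adjusted p = 0.0036, but adjusted p = 0.056 with an estimated correlation). CYP71P1, which hydroxylates tryptamine to serotonin, rose by 1.65.

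Several lists of growth genes fell in Nipponbare. Of 82 genes of the cell cycle and histones 23 fell and 0 rose (32 fell and 1 rose adjusted over the list alone; adjusted p = 9.2e-12, and adjusted p = 0.036 with an estimated correlation), among them the kinesin gene KIN13B, which fell by 0.67 on the log2 scale. Of 26 expansins, which loosen cell walls, 7 fell (11 fell and 1 rose adjusted over the list alone; adjusted p = 1.7e-06, and adjusted p = 0.036 with an estimated correlation), and OsEXPB2 fell by 0.85. Of 32 cellulose synthases and related genes 15 fell and 1 rose (15 and 4 adjusted over the list alone; adjusted p = 2.4e-06, but adjusted p = 0.051 with an estimated correlation), and OsCesA6 fell by 0.54. Of 65 auxin genes 13 fell and 4 rose (20 and 4 adjusted over the list alone; adjusted p = 8.2e-06, and adjusted p = 0.036 with an estimated correlation). IAA1, of the repressors of auxin response, fell by 0.61, and OsGH3-8, which conjugates auxin, rose by 1.13. Of 21 cytosolic ribosomal proteins 0 were called by limma (0 adjusted over the list alone, 3 at an unadjusted p below 0.05; adjusted p = 0.019, but adjusted p = 0.74 with an estimated correlation and 0.12 after quantile normalization).

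In total 2054 probe sets rose and 1689 fell in Nipponbare, and 1018 rose and 100 fell at least 2-fold. Over days 2 and 4 alone, an average added after seeing the data that rests on 8 of the 12 arrays, 482 rose and 108 fell, and 26 of the 49 named results, among them those of IAA1, OsCesA6, OsEXPB2, OsSWEET1a and CYP99A2, were no longer called. Leaving out replicate 1 of the infected roots of day 2 gave 2470 calls, and centring on the median of all probe sets, also added, gave 998 higher and 7509 lower.

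The mean infection effect in IAC165 asks the same of the susceptible cultivar. PBZ1 rose from a signal of 91.2 ± 30.8 in 6 mock arrays to 2881 ± 1729 in 6 infected arrays, by 4.84 ± 0.44 on the log2 scale (adjusted p = 5.4e-07). OsCPS4, a diterpene cyclase of phytoalexin synthesis, rose by 3.74 ± 0.31 (adjusted p = 2.0e-07; 3.47 when floored). The laccase genes LAC19 and LAC15, of the oxidases that polymerise lignin precursors, rose by 3.55 ± 0.24 (adjusted p = 2.1e-08; 3.45 when floored) and 3.33 ± 0.29 (adjusted p = 3.3e-07; 2.66 when floored). Another laccase gene, LAC3, fell by 1.73 on the log2 scale (adjusted p = 5.0e-08), OsSWEET1a fell by 2.36 (adjusted p = 4.0e-06) and ILL3, of a family that frees auxin from conjugates, fell by 1.88 (adjusted p = 3.2e-06).

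Of the 15 genes of diterpenoid phytoalexins 12 rose in IAC165 (13 adjusted over the list alone; adjusted p = 3.5e-09, but adjusted p = 0.062 with an estimated correlation). Mock signals of several members lay below 20.5. CYP99A2 rose by 3.99 but by 2.75 when floored, OsDTS2 by 3.82 but by 0.93, and OsCPS2 was at least 3.34-fold higher. Of 34 jasmonate genes 15 rose and 2 fell (15 and 2 adjusted over the list alone; adjusted p = 7.4e-05, but adjusted p = 0.17 with an estimated correlation), with a rise of 3.44 for OsJAZ11 that was 1.56 when floored. Of 11 chitinases and glucanases 5 rose (5 adjusted over the list alone; adjusted p = 0.0054, but adjusted p = 0.20 with an estimated correlation), with a rise of 2.86 for OsChia1a. Of 10 PDR and ABCG transporters 5 rose and 1 fell (5 and 1 adjusted over the list alone; adjusted p = 0.055), of 27 cytochrome P450 genes 12 rose and 4 fell (12 and 6 adjusted over the list alone; adjusted p = 0.055), and of 6 WRKY factors 3 rose (5 rose and 1 fell adjusted over the list alone; adjusted p = 0.072), so that these lists were not called.

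Of 82 genes of the cell cycle and histones 36 fell and 4 rose in IAC165 (47 and 4 adjusted over the list alone; adjusted p = 1.6e-14, but adjusted p = 0.051 with an estimated correlation). OsRPA32, a subunit of the replication protein that binds single-stranded DNA, fell by 1.02 on the log2 scale. Of 26 expansins 14 fell and 1 rose (17 and 1 adjusted over the list alone; adjusted p = 1.3e-10, and adjusted p = 0.025 with an estimated correlation), and OsEXPB6 fell by 1.16. Of 32 cellulose synthases and related genes 12 fell and 4 rose (13 and 5 adjusted over the list alone; adjusted p = 1.2e-05, but adjusted p = 0.13 with an estimated correlation), and OsCesA6 fell by 0.84. Of 65 auxin genes 14 fell and 7 rose (16 and 7 adjusted over the list alone; adjusted p = 0.010, but adjusted p = 0.17 with an estimated correlation and 0.058 after quantile normalization). Of 21 ribosomal proteins 6 fell and 1 rose (9 and 1 adjusted over the list alone; adjusted p = 0.0011, but adjusted p = 0.54 with an estimated correlation).

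In total 3580 probe sets rose and 3517 fell in IAC165, and 1399 rose and 636 fell at least 2-fold. Over days 2 and 4 alone, the average added after seeing the data, 1635 rose and 1879 fell, and 9 of the 57 named results were no longer called. Centring on the median of all probe sets, added after seeing the data, gave 1271 higher and 7107 lower and ended the calls of 10 of the 57 genes named, among them OsEXLA4 (adjusted p = 0.064). In both cultivars no called list had a median, mean and test that differed in sign.

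**Figure D2:**
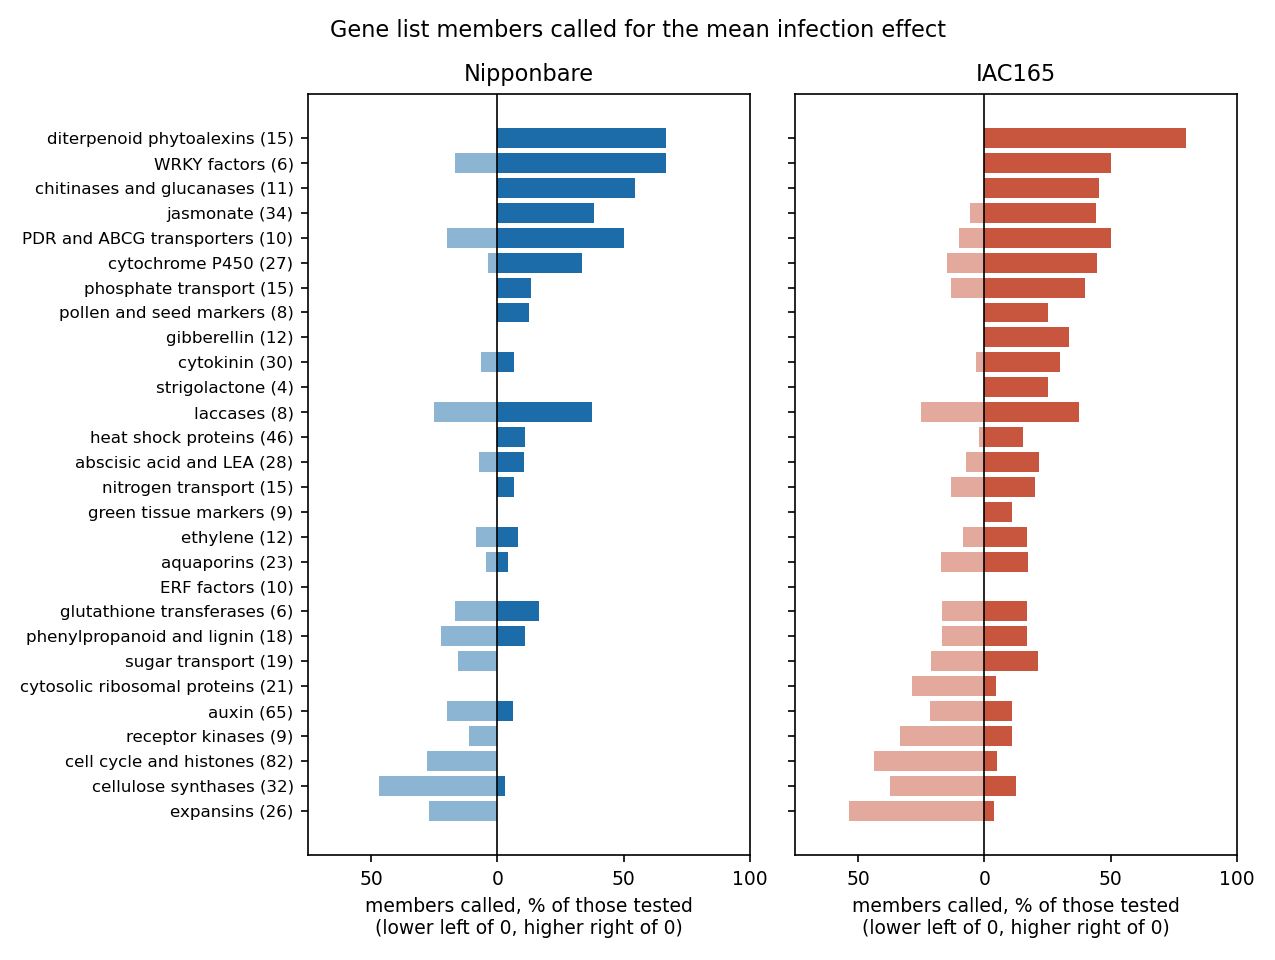
Bars give the members of each gene list (number tested in brackets) called for the mean infection effect, in % of those tested, with lower members left of 0 and higher members right of 0, for Nipponbare (left panel) and IAC165 (right panel). Defence lists at the top lie mostly to the right of 0 and growth lists at the bottom mostly to the left, with 10 and 12 of 15 phytoalexin genes higher. Calls depend on the scaling: centring on the median of all probe sets gave 998 higher and 7509 lower in Nipponbare and 1271 and 7107 in IAC165. No list call reversed under that centring. It shifts all probe sets of an array alike, so it hardly bears on a test against all other probe sets.

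The remaining lists were not called in either mean effect (adjusted p between 0.12 and 0.95 in Nipponbare and up to 0.97 in IAC165). In IAC165, 9 of 30 cytokinin genes rose and 1 fell, 6 of 15 genes of phosphate transport rose and 2 fell, 4 of 12 gibberellin genes rose, 6 of 28 genes of abscisic acid and LEA proteins rose and 2 fell, and 7 of 46 heat shock genes rose and 1 fell. In Nipponbare the same lists had 2 higher and 2 lower, 2 higher, 0, 3 higher and 2 lower, and 5 higher; of the gibberellin genes 3 passed an unadjusted p below 0.05 in limma. LOGL9, of the cytokinin-activating enzymes, rose by 2.43 ± 0.23 in Nipponbare and 2.61 ± 0.23 in IAC165 (2.36 and 2.13 when floored), and OsPHR3, a regulator of phosphate starvation responses, by 1.17 and 0.95. Over these lists without a call 22 members rose and 17 fell in Nipponbare (26 and 24 adjusted over the list alone), and 77 rose and 31 fell in IAC165 (89 and 40), the last figures including the WRKY, PDR and P450 lists.

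Of 8 laccases 3 rose and 2 fell in each cultivar. Of 19 genes of sugar transport 0 rose and 3 fell in Nipponbare and 4 rose and 4 fell in IAC165, where OsSUT1, a sucrose transporter, rose by 1.39. Of 23 aquaporins 1 rose and 1 fell in Nipponbare and 4 rose and 4 fell in IAC165. Of 15 genes of nitrogen transport 1 rose in Nipponbare, and 3 rose and 2 fell in IAC165. Of 18 phenylpropanoid and lignin genes 2 rose and 4 fell in Nipponbare and 3 rose and 3 fell in IAC165. The 2 class III peroxidases with a gene name in the list fell in both cultivars, with PRX112 lower by log2 changes of -0.86 and -1.47. Of 12 ethylene genes 1 rose and 1 fell in Nipponbare and 2 rose and 1 fell in IAC165; of 6 glutathione transferases 1 rose and 1 fell in each. Of 9 receptor kinases and pattern receptors 1 fell in Nipponbare and 1 rose and 3 fell in IAC165, and OsCEBiP, a chitin receptor, changed by -0.55 and -0.66. Strigolactone genes had 0 of 4 higher in Nipponbare (2 at an unadjusted p below 0.05 in limma) and 1 in IAC165. Of the 10 ERF factors with a gene name in the list limma called 0 in either cultivar (3 in Nipponbare and 2 in IAC165 at an unadjusted p below 0.05). The PR protein list held PBZ1 alone, the NBS-LRR list held 1 gene with 0 calls in limma (0 at an unadjusted p below 0.05), and the glycosyltransferase list had no member on the array's annotation. Lists of markers of tissues other than roots moved little: of 9 green tissue markers 0 were called in Nipponbare (1 at an unadjusted p below 0.05 in limma) and 1 rose in IAC165, and of 8 pollen and seed markers 1 rose in Nipponbare and 2 in IAC165.

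The effects were also tested by day, first in Nipponbare. The main model gives all 12 groups 1 spread per probe set. The SD of the log2 difference between replicates was 0.25 in both groups at day 2. At day 11 it was 0.40 in mock and 0.51 in infected roots. A model of the compared groups alone, with fewer residual degrees of freedom, gave 484, 269 and 551 calls by day, against 61, 413 and 2786. The counts by day therefore do not show when genes responded. At day 2, with 2 arrays per group, LAC19 rose by 2.58 ± 0.42 (adjusted p = 0.011), or by 2.56 when floored, and LOGL9 by 2.53. OsZIP4 was lower, at 329 ± 120 against 963 ± 22.8. PBZ1 was not called at day 2: its signal was 2495 ± 1385 in infected roots and already 2165 ± 104 in mock roots, against 175 ± 86.5 in mock roots at day 4. At day 2, 58 probe sets rose and 3 fell; without any 1 of the 4 arrays 8 to 23 were called, while array weights gave 502 calls and a model of the compared groups alone gave 484. Each of the 6 genes named for that day lost its call in at least 3 of the 4 runs.

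At day 4, PBZ1 reached 4542 ± 43.4 in infected Nipponbare roots, a rise of 4.80 ± 0.76 (adjusted p = 0.0025). Genes of phytoalexin enzymes rose with it: CYP71Z7 had 724 ± 46.9 against 27.8 ± 4.03. Cht11 was at least 6.84-fold higher, with 142 ± 30.5 against 12.2 ± 5.37. The phytoalexin list had 5 of 15 members higher (11 adjusted over the list alone; adjusted p = 1.2e-10, but adjusted p = 0.082 with an estimated correlation). Of all probe sets 348 rose and 65 fell. Without any 1 of the 4 arrays the count was 136 to 294 and 8 of the 10 genes named for that day lost their call, among them CYP71Z7 in 2 of 4 runs (adjusted p up to 0.0802) but not PBZ1 or Cht11; centring on the median of all probe sets gave 103 higher and 91 lower.

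At day 11, Cht11 in Nipponbare stood at 1126 ± 156 in infected roots against 15.1 ± 4.45 in mock roots, at least 54.7-fold higher. OsNIP1;1 stood at 1630 ± 323 against 33.8 ± 7.42, a rise of 5.60 ± 0.35 (adjusted p = 2.5e-08), and OsNSHB1, a non-symbiotic haemoglobin, at 2638 ± 413 against 64.4 ± 23.3, a rise of 5.40 ± 0.39 (adjusted p = 9.2e-08). OsSTLP2 fell by 1.74 on the log2 scale. Of the cell cycle and histone genes 27 of 82 fell (38 adjusted over the list alone; adjusted p = 1.6e-13, and adjusted p = 0.028 with an estimated correlation). The totals were 1284 higher and 1502 lower. Without replicate 2 of the infected roots the count was 1376 and without replicate 1 it was 4036. A model of the compared groups alone gave 418 higher and 133 lower, and centring on the median of all probe sets gave 596 and 3598.

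The change from day 2 to day 11 tests whether the effect in Nipponbare moved with time. The infection effect on Cht11 rose by 5.97 ± 0.63 (adjusted p = 3.6e-04; 5.49 when floored, as mock roots at day 11 lay below 20.5) and on OsNSHB1 by 4.90 ± 0.55 (adjusted p = 4.7e-04). These calls held without any 1 of the 8 arrays and under centring on all probe sets. It rose by 3.60 ± 0.65 on OsDTC1, a diterpene cyclase, and changed by -1.64 ± 0.30 on the expansin gene OsEXP1, but these calls were lost in 5 of 8 runs without 1 array (adjusted p up to 0.10 and 0.12). The phytoalexin list moved up, with 2 of 15 members called (5 adjusted over the list alone; adjusted p = 1.0e-08, but adjusted p = 0.074 with an estimated correlation), and the expansins moved down, with 2 of 26 called (5 adjusted over the list alone; adjusted p = 5.9e-06, but adjusted p = 0.074 with an estimated correlation). Of all probe sets 92 had a higher and 58 a lower effect at day 11. Without replicate 2 of the mock roots of day 2 the count was 61 and without replicate 1 of the infected roots of day 11 it was 926; centring on the median of all probe sets gave 24 and 3.

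In IAC165 at day 2, PBZ1 had 1248 ± 23.7 in infected and 102 ± 45.9 in mock roots (n = 2 each), a rise of 3.69 ± 0.76 (adjusted p = 0.014). OsCPS4 was at least 14.2-fold higher, with 295 ± 61.7 against 15.2 ± 1.70. The phosphate transporter gene OsPht1;2 fell by 1.35 on the log2 scale and the nitrate transporter gene OsNRT2.3 by 1.41. Of 34 jasmonate genes 10 rose (14 rose and 1 fell adjusted over the list alone; adjusted p = 2.0e-06, but adjusted p = 0.16 with an estimated correlation). The totals were 458 higher and 299 lower. Without any 1 of the 4 arrays the count was 362 to 743 and 8 of the 10 named genes lost their call, with adjusted p up to 0.101 for PBZ1 and 0.138 for OsNRT2.3; centring on the median of all probe sets gave 183 higher and 257 lower.

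At day 4 in IAC165, OsSWEET1a had a signal of 106 ± 25.2 in infected roots against 1117 ± 360 in mock roots, and LAC3 had 219 ± 33.7 against 1174 ± 135. PBZ1 had 3087 ± 1174 against 77.5 ± 44.3, and LAC15 was at least 8.08-fold higher. The ribosomal protein genes fell at this day, 13 of 21 (17 adjusted over the list alone; adjusted p = 7.5e-12, but adjusted p = 0.17 with an estimated correlation), and so did 10 of 26 expansins against 1 that rose (14 and 1 adjusted over the list alone; adjusted p = 5.6e-10, and adjusted p = 0.034 with an estimated correlation). Limma called 1528 higher and 1983 lower. Without any 1 of the 4 arrays the count was 1521 to 2520, the lowest without replicate 2 of the mock roots; centring on the median of all probe sets gave 484 higher and 1180 lower.

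At day 11 in IAC165, PBZ1 had 4309 ± 2020 in infected roots against 94.2 ± 7.21 in mock roots. The actin-severing factor gene OsADF1 fell by 2.95 on the log2 scale (2.49 when floored) and OsC3H23, a zinc finger protein gene, was at least 3.50-fold lower. Of 15 phytoalexin genes 9 rose (13 adjusted over the list alone; adjusted p = 8.9e-09, but adjusted p = 0.071 with an estimated correlation), and 33 of 82 genes of the cell cycle and histones fell (38 fell and 2 rose adjusted over the list alone; adjusted p = 6.0e-15, and adjusted p = 0.047 with an estimated correlation). In these infected roots a control probe set for 18S ribosomal RNA had signals of 331 and 385, against 48.7 or less on the 22 other arrays. Of all probe sets 1799 rose and 1957 fell. Without any 1 of the 4 arrays the count was 1573 to 2352, the lowest without replicate 2 of the mock roots; centring on the median of all probe sets gave 641 higher and 5451 lower.

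From day 2 to day 11 the infection effect in IAC165 rose by 4.93 ± 1.07 on DREB1B, a cold-induced transcription factor gene (adjusted p = 0.036; 4.55 when floored), and changed by -2.52 ± 0.49 on OsCHS1, which encodes chalcone synthase, an enzyme of flavonoids (adjusted p = 0.023), and by -1.87 ± 0.35 on the cellulose synthase gene OsCesA4 (adjusted p = 0.019). OsCHS1 stood at 1558 ± 329 in infected against 324 ± 36.0 in mock roots at day 2 and at 241 ± 7.21 against 290 ± 36.0 at day 11. Of 15 genes of nitrogen transport and assimilation the effect on 3 rose (5 rose and 1 fell adjusted over the list alone; adjusted p = 0.0014, but adjusted p = 0.090 with an estimated correlation). Among probe sets, 186 had a higher and 182 a lower effect at day 11. Without replicate 2 of the mock roots of day 11 the count was 65 and without replicate 1 of the mock roots of day 2 it was 684, and each of the 6 genes named lost its call in at least 1 of the 8 runs, with adjusted p up to 0.158 for DREB1B, 0.0986 for OsCHS1 and 0.101 for OsCesA4; centring on the median of all probe sets gave 27 and 41.

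**Figure D3:**
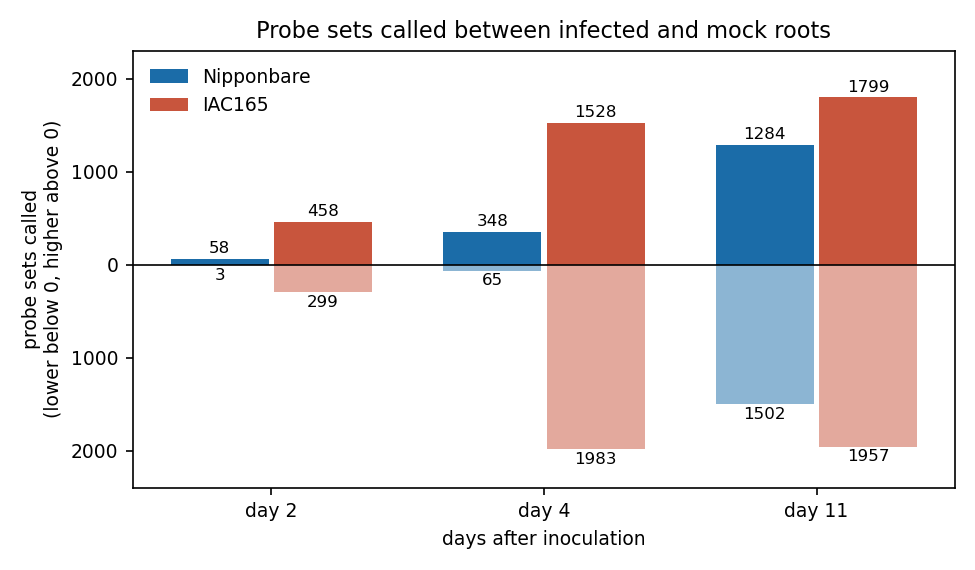
Bars give the number of probe sets called higher (above 0) or lower (below 0) in infected than in mock roots at days 2, 4 and 11 in Nipponbare (blue) and IAC165 (red). The bars run from 58 higher and 3 lower in Nipponbare at day 2 to 1799 higher and 1957 lower in IAC165 at day 11; the balance at day 11 turned with the setting, with 596 higher and 3598 lower in Nipponbare and 641 and 5451 in IAC165 under centring on the median of all probe sets, but 1398 and 1336, and 1954 and 1811, under centring on the median of the bright ones.

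The effects in the cultivars went largely the same way. On the average over days 1231 probe sets rose in both, where 190 would fall together by chance, 1257 fell in both (154 by chance), and 10 were called in opposite directions (343 by chance). Of the probe sets called in IAC165, 92.3% had the same sign in Nipponbare, and of those called in Nipponbare 95.8% had the same sign in IAC165. Over the probe sets called in IAC165, the slope of the Nipponbare effects on those of IAC165 was 0.56. Choosing probe sets by their IAC165 calls lowers this slope, and none was fitted over the Nipponbare calls. It therefore does not show a weaker response in Nipponbare. Pearson's r between the effects, across probe sets of 1 set of arrays, which are not independent replicates, was 0.19 at day 2, 0.27 at day 4, 0.44 at day 11 and 0.55 on average, and 0.40, 0.52, 0.71 and 0.75 among the brighter probe sets.

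The difference of the infection effects between cultivars was tested directly. With 1 resistant and 1 susceptible cultivar it compares these 2 cultivars and not resistance itself. At day 11 Cht11 had 1126 ± 156 in infected roots of Nipponbare and 71.8 ± 39.7 in those of IAC165, with mock roots at 15.1 ± 4.45 and 18.4 ± 2.47, a difference in effect of 4.40 ± 0.63 (adjusted p = 0.0071). As both mock groups lay below 20.5, it was 4.08 when floored. OsChia1c went from 35.6 ± 11.0 to 444 ± 54.2 in Nipponbare and from 23.8 to 34.0 in IAC165. This was a difference of 3.07 ± 0.50 (adjusted p = 0.017), or 3.28 when floored. Over the 3 days it was also higher in mock roots of Nipponbare than of IAC165, by 0.94 (adjusted p = 0.0027), or 0.87 when floored. A part of probe sequence differences between the cultivars in these differences of effect was not tested. OsNIP1;1 had a difference of 3.18 ± 0.50 at that day (adjusted p = 0.015), and OsGLN1;2, a glutamine synthetase gene, had -0.99 ± 0.17 (adjusted p = 0.019). Of the 8 runs that left out 1 array, OsNIP1;1 lost its call in 2, OsChia1c in 3 and OsGLN1;2 in 6, with adjusted p up to 0.0650, 0.0716 and 0.0890, while Cht11 kept its call. Averaged over days the effect on OsWRKY76 was higher in Nipponbare by 1.49 ± 0.25 (adjusted p = 0.018), and on Cht11 and OsChia1c by 2.27 ± 0.37 and 2.03 ± 0.29 (adjusted p = 0.015 and 0.0070; 1.98 and 2.10 when floored).

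Genes whose infection effect was lower in Nipponbare than in IAC165 on average were OsMT-2, a metallothionein gene, at -0.96 ± 0.13 (adjusted p = 0.0050), OsCHS1, at -1.46 ± 0.29 (adjusted p = 0.035), and the expansin-like gene OsEXLA4, at -1.21 ± 0.25 (adjusted p = 0.042). Without 1 array OsCHS1 lost its call in 15 and OsEXLA4 in 20 of 24 runs, with adjusted p up to 0.0808 and 0.0913. The genes LAC3 and OsEXPB6, which fell in IAC165, had differences of 1.13 ± 0.18 and 0.89 ± 0.13 (adjusted p = 0.015 and 0.0070). Among called probe sets with a named gene, the largest difference at day 4 was that of ILL3, 3.03 ± 0.49 (adjusted p = 0.019; lost in 3 of 8 runs without 1 array, with adjusted p up to 0.0885), with 352 ± 117 in infected and 270 ± 0.566 in mock roots of Nipponbare and 275 ± 103 and 1724 ± 386 in IAC165. OsCIPK25, a kinase gene of calcium signalling, followed with 2.60 ± 0.33 (adjusted p = 0.0041). Among the lists, the effect on expansins was higher in Nipponbare on average, with 1 member called in each direction (8 higher and 1 lower adjusted over the list alone; adjusted p = 7.5e-05, but adjusted p = 0.30 with an estimated correlation). Every other list called for a cultivar difference also lost its call with an estimated correlation, with adjusted p from 0.10 for nitrogen transport at day 2 to 0.91 for the cell cycle on average.

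For the cultivar difference limma called 0 probe sets at day 2, where OsPht1;2 had 1.90 ± 0.29 (adjusted p = 0.11). At an unadjusted p below 0.05 limma had 2205 probe sets there, near the 1934.7 expected by chance. It called 63 higher and 32 lower in Nipponbare at day 4, 45 and 15 at day 11, and 78 and 66 on average. Without 1 array the counts moved to 0 to 39 at day 2 (39 without replicate 2 of infected IAC165), 4 to 109 at day 4 (4 without replicate 1 of mock Nipponbare), 16 to 213 at day 11 (16 without replicate 1 of mock IAC165 and 213 without replicate 1 of infected Nipponbare) and 35 to 187 on average (35 without replicate 1 of infected Nipponbare at day 2). Over days 2 and 4 alone 32 were higher and 30 lower on average, and 6 of the 10 genes named lost their call. A model of the compared groups alone gave 0 calls in limma at day 4, so that all 6 genes named for that day, ILL3 and OsCIPK25 among them, lost their call. It gave 9 calls at day 11, where 3 of 4 named genes lost it and OsNIP1;1 kept it. With a replicate block within cultivar and day the calls were 10 at day 4, 22 at day 11 and 28 on average. Under that block 5 of the 6 genes named for day 4, 2 of the 4 for day 11 and 6 of the 10 for the average lost their call. Without the intensity trend the calls were 8 at day 4, 22 at day 11 and 13 on average. Then 5 of the 6 genes named for day 4, all but OsCIPK25, 3 of the 4 for day 11, all but Cht11, and 7 of the 10 for the average lost their call, while OsWRKY76, OsChia1c and OsMT-2 kept theirs on average. Centring on the median of all probe sets ended the calls of 7 of the 10 genes named for the average, leaving those of Cht11, OsChia1c and OsMT-2, of all 6 named for day 4 and, among those for day 11, of OsGLN1;2 (adjusted p = 0.74).

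**Figure D4:**
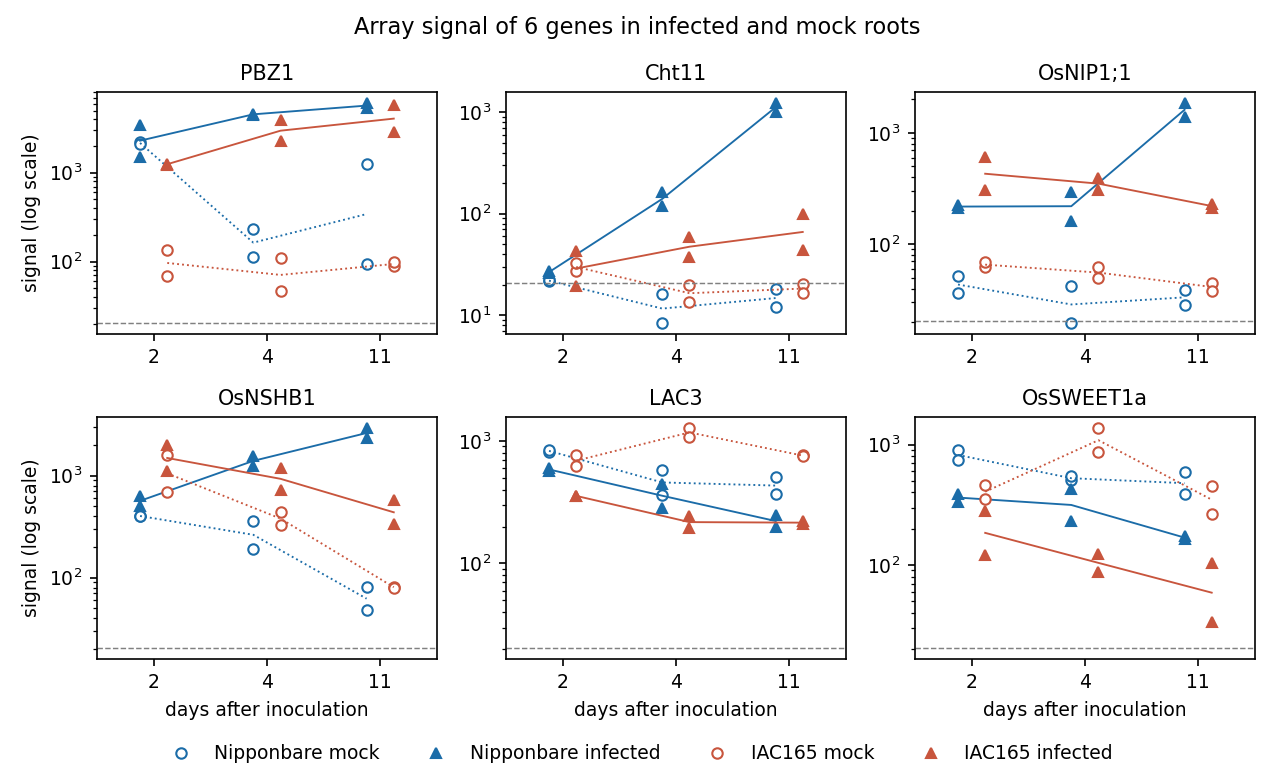
Each point is the signal of 1 array (log scale) for 6 genes against days after inoculation, filled triangles for infected and open circles for mock roots, blue for Nipponbare and red for IAC165, with lines through the group means of log signal and a dashed line at 20.5. Cht11, OsNIP1;1 and OsNSHB1 reach 1126, 1630 and 2638 in infected Nipponbare at day 11, while LAC3 and OsSWEET1a are lower in infected than in mock IAC165 on each day.

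Mock roots of the cultivars differed in many genes without infection. OsPP2C12, a protein phosphatase gene, had 1274 ± 279 in 6 mock arrays of Nipponbare and 56.5 ± 8.77 in 6 of IAC165, a difference of 4.48 ± 0.13 (adjusted p = 5.0e-14), and OsMADS56, a MADS-box factor gene, was at least 5.19-fold higher in Nipponbare. The chitinase gene listed as Cht1 was at least 36.2-fold lower in Nipponbare, with 3.62 ± 3.38 against 863 ± 551, and OsBURP02 had a difference of -5.65 ± 0.50 (adjusted p = 1.3e-07; -5.52 when floored). Of 15 phytoalexin genes 8 were higher in Nipponbare (10 adjusted over the list alone; adjusted p = 5.1e-05, but adjusted p = 0.44 with an estimated correlation), and of 30 cytokinin genes 8 were higher and 1 lower (10 and 2 adjusted over the list alone; adjusted p = 0.011, but adjusted p = 0.44 with an estimated correlation). Of 26 expansins 10 were lower and 1 higher (11 and 1 adjusted over the list alone; adjusted p = 0.0041, but adjusted p = 0.44 with an estimated correlation). In all, 8 lists were called and 0 with an estimated correlation.

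Among probe sets, 3865 were higher and 3749 lower in mock roots of Nipponbare, and 1580 were higher and 831 lower at least 2-fold. Differences in probe sequence between the cultivars can give such calls, and 33 genes had probe sets called in opposite directions; centring on the median of all probe sets gave 3922 higher and 1268 lower.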

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

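The tests of the 18S ribosomal RNA signal below were chosen after the signal was seen, as were the values with signals below 20.5 set to 20.5, and the tests of differences between cultivars and days were planned. Groups of 2 arrays were not tested for a sample far from the others.

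Differences of the infection effect between cultivars, tested directly, reached the threshold for 95 probe sets at day 4. Among them, as Nipponbare minus IAC165 on the log2 scale, were ILL3 (3.03), OsCIPK25 (2.60), OsChia1c (2.48), LAC3 (2.07), the transporter gene OsABCG5 (2.03), OsEXPB6 (1.53), PRX112 (1.33) and OsRPA32 (1.18), and on the other side the zinc finger gene OsC3H55 (-1.50), OsMT-2 (-1.35) and LOGL1 (-1.13). At day 11, with 60 probe sets, they included Cht11 (4.40), OsNIP1;1 (3.18), OsChia1c (3.07), OsNSHB1 (2.96) and OsGLN1;2 (-0.99). On average, with 144 probe sets, they included Cht11 (2.27), OsChia1c (2.03), OsWRKY76 (1.49), LAC3 (1.13), OsEXPB6 (0.89), OsC3H55 (-0.90), OsMT-2 (-0.96), the calmodulin-like gene CML29 (-0.98), OsPP2C12 (-0.98), OsEXLA4 (-1.21) and OsCHS1 (-1.46, and -1.14 on a second probe set). In runs without 1 array 10 of the 11 listed for day 4, all but OsCIPK25, 4 of the 5 for day 11, all but Cht11, and 6 of the 12 for the average were lost at least once. On average CML29 was lost in 21, OsEXLA4 in 20, OsCHS1 in 15 (22 on the second probe set), OsPP2C12 in 13 and OsC3H55 in 6 of 24 runs. At day 4 OsChia1c, OsC3H55 and OsRPA32 were lost in 7, LOGL1 and PRX112 in 6, OsABCG5 in 4, ILL3, LAC3 and OsMT-2 in 3 and OsEXPB6 in 1 of 8 runs. At day 11 OsGLN1;2 was lost in 6, OsNSHB1 in 5, OsChia1c in 3 and OsNIP1;1 in 2 of 8. With signals below 20.5 set to 20.5 the values of Cht11 were 4.08 at day 11 and 1.98 on average.

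The effect also differed between day 2 and day 11, tested directly, for 150 probe sets in Nipponbare. Higher at day 11 were Cht11 (5.97), OsNSHB1 (4.90, and 4.52 on a second probe set), OsDTC1 (3.60), OsNIP1;1 (3.27), OsChia1a (3.21), CYP99A3 (2.89), OsChia1c (2.71), OsABCG44 (2.42) and OsMT-2 (1.16), and lower were OsEXP1 (-1.64), a peroxidase gene (-1.55), OsEXPB2 (-1.45), OsPht1;2 (-1.39) and IAA1 (-1.20). Of these 15 calls 11 were lost in at least 1 of 8 runs without 1 array: OsEXPB2 in 7, OsPht1;2 and OsMT-2 in 6, OsDTC1, OsEXP1, OsChia1c, OsABCG44, CYP99A3 and IAA1 in 5, the peroxidase in 4 and the second probe set of OsNSHB1 in 1. In IAC165, with 368 probe sets, DREB1B (4.93), OsNSHB1 (3.52), the calmodulin-like gene CML16 (2.88), OsNRT2.3 (1.83), the glutaredoxin gene GRXS5 (1.45) and OsGLN1;2 (0.93) were higher at day 11. OsC3H23 (-3.33), OsCHS1 (-2.52), OsCesA4 (-1.87), OsHsp17.9B (-1.18), KIN13B (-1.15), OsEXPB6 (-1.11), GST1 (-1.10), OsRPA32 (-1.07) and OsCesA6 (-0.91) were lower. All 15 of these calls were lost in at least 1 of 8 runs, from 2 for GST1 to 6 for DREB1B. With signals below 20.5 set to 20.5 the values were 5.49 for Cht11 and 3.55 for OsDTC1 in Nipponbare. In IAC165 they were 4.55 for DREB1B, 2.22 for OsNSHB1 and -1.68 for OsC3H23.

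Control probe sets, which the comparisons above did not use, had signals above those of the mock arrays in some infected groups. In infected IAC165 at day 11 the mean was 358 for an 18S ribosomal RNA, 38.1 for a second 18S and 111.1 for a 28S probe set. The 28S mean was 41.75 in infected Nipponbare at day 4. A control for a fungal elongation factor had means of 57.25 and 76.1 in infected IAC165 at days 2 and 11 and of 73.35 and 80.35 in infected Nipponbare at days 4 and 11. The spiked-in controls had geometric means of 3661.6 in infected IAC165 at day 11 and 2673.24 in infected Nipponbare at day 4.

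The 18S signals of 331.4 and 384.6 in infected IAC165 at day 11 stood against at most 48.7 on the other 22 arrays. A weaker rice signal on these arrays, scaled up afterwards, would raise the spiked-in controls as much. Taken as the lower of the 2 arrays over the highest other array, the controls rose 1.11-fold. The 18S rise was 6.12 times theirs, which argues against a weaker rice signal as the whole source. Hybridisation that weakened rice and spiked-in RNA alike would not show in these controls and was not tested. RNA degradation was left open, since 3 of the 4 ratios of 3' to 5' signal lay inside the range of the other 22 arrays and 1, for GAPDH, lay just above. Ribosomal RNA of the attached parasite is a candidate source: 2 of the 4 other ribosomal probe sets were above all other arrays on both arrays and 2 were not, which left it undecided. A change in the ribosomal RNA of the host stays open as untested.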

How the results depend on the processing

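The centrings, the average over days 2 and 4, and the crossed replicate block were chosen after the results were seen, and the other alternatives were planned. Apart from leaving out arrays, 136 alternative counts stayed within 1.5 times the main value and 58 moved further. Of 207 gene results 204 were called in the main model. Of these 103 were called under all these settings, the 2-fold threshold aside, and 101 lost their call under at least 1. Without 1 array 67 lost it at least once and 0 reversed.

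The plan's rule on centring was read on the brighter probe sets, whose medians differed by 0.073, and not on all probe sets, whose medians differed by 0.77. Centring on all probe sets, the other reading, gave 25, 194 and 4194 calls in Nipponbare at days 2, 4 and 11, 440, 1664 and 6092 in IAC165, and 8507 for the mean in Nipponbare. It left 3, 21 and 14 for the cultivar difference at day 4, at day 11 and on average, and 27 and 68 for the change from day 2 to day 11 in Nipponbare and IAC165. The balance of rises and falls therefore depended on the scaling.

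The filter on dim probe sets moved the correlation of effects between cultivars. Without a filter it was 0.16 at day 4, 0.29 at day 11 and 0.39 on average, with 76 calls for the mean cultivar difference; with the stricter filter it was 0.44, 0.58, 0.71 and 0.76 at days 2, 4 and 11 and on average, with 145 calls for the difference at day 4.

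Without the intensity trend the calls were 12 and 274 in Nipponbare at days 2 and 4, 451 in IAC165 at day 2, 8, 22 and 13 for the cultivar difference at day 4, at day 11 and on average, and 57 and 45 for the change in Nipponbare and IAC165. Array weights gave 502, 840 and 1393 in Nipponbare by day, 272 in IAC165 at day 2, 192 and 27 for the difference at days 4 and 11, and 194 for the change in IAC165. A 2-fold threshold gave 1695 in Nipponbare at day 11, 1637 and 2165 in IAC165 at days 4 and 11, 1118 and 2035 for the means, 79 for their difference and 2411 for mock roots.

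A model of the compared groups alone gave 484, 269 and 551 in Nipponbare by day, and 264 and 2260 in IAC165 at days 2 and 4. It gave 14, 0 and 9 for the difference by day in limma, and 72 and 54 for the change. With a replicate block within cultivar and day the calls were 263 in Nipponbare at day 4, 10, 22 and 28 for the difference at day 4, at day 11 and on average, and 64 and 175 for the change; with a block over all arrays there was 1 for the difference at day 2. Over days 2 and 4 alone the means had 590 and 3514 calls and their difference 62.

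Without 1 array the counts ran from 8 to 23 in Nipponbare at day 2, 136 to 294 at day 4 and 1376 to 4036 at day 11, and in IAC165 from 362 to 743, 1521 to 2520 and 1573 to 2352. The cultivar difference ran from 0 to 39, 4 to 109 and 16 to 213 by day and 35 to 187 on average, and the change from 61 to 926 in Nipponbare and 65 to 684 in IAC165. The mean effects had 2470 to 5104 and 5414 to 7915 calls, and mock roots 5982 to 7547.

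The 28 gene lists were tested for the mean effect of each cultivar, and a list called in both cultivars counts once for each. Counted so, 19 list results were called, 11 in Nipponbare and 8 in IAC165. With an estimated correlation 8 were called, 7 in Nipponbare and 1 in IAC165, and by fry 31 over both cultivars.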

Other observations

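The tests of brighter probe sets, of sibling probe sets and of other splits of the samples were chosen before their results were seen.

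Genes of phosphate transport and its regulation leaned upward in Nipponbare at day 2, as a list (adjusted p = 2.8e-04, and adjusted p = 0.022 with an estimated correlation), although limma called 0 of 15 members (1 adjusted over the list alone, 5 at an unadjusted p below 0.05). In IAC165 at day 4, 8 of 30 cytokinin genes rose (8 adjusted over the list alone; adjusted p = 0.0036, but adjusted p = 0.17 with an estimated correlation). OsPSY2, a phytoene synthase gene of carotenoid synthesis, was at least 2.74-fold lower in infected Nipponbare roots at day 4, and OsAPY3, an apyrase gene, was at least 4.06-fold higher in infected IAC165 roots at day 2. Both calls were lost without 1 of their arrays, with adjusted p up to 0.154 and 0.0515.

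Calls were shared between days. In Nipponbare 270 probe sets rose and 44 fell at both day 4 and day 11, where 11.5 and 2.52 would by chance, and in IAC165 626 rose and 1067 fell (71.0 and 100 by chance), with 0 and 4 called in opposite directions.

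Rises of at least 2-fold outnumbered falls in infected Nipponbare roots, 1018 to 100. Over all calls the balance depended on the scaling and the filter, and 2054 rose and 1689 fell in the main model. After quantile normalization the counts were 1525 and 1651, and with centring on the median of all probe sets 998 and 7509. With the stricter filter on dim probe sets 1512 rose and 1958 fell. A higher background on infected arrays could raise dim probe sets. Most of the 2-fold calls, 812 rises and 82 falls, lay in probe sets with a mean signal at or below the pooled 75th percentile. Above it the ratio of rises to falls was 11.4, 206 to 18, which argues against background as the whole source. For the dimmer probe sets the part of background was not separated. No biological explanation was tested beyond the infection itself.

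Probe sets brighter in mock roots of Nipponbare by at least 2-fold outnumbered those brighter in IAC165, 1580 to 831. Sequence differences under the probes are a candidate explanation for such calls: of sibling probe sets of the same genes 67 of 156 followed, 42.9%, against 122 of 173 for infection calls, a difference of -27.6 percentage points. Siblings of calls lower in Nipponbare followed in 20 of 55 cases, so the test bears on calls in both directions and not on the excess itself. A difference in expression between the cultivars stays open as untested.

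Of 100 splits of the arrays drawn for each result, only 1, the real one, gave as many calls. Splits were drawn for the main model alone. For the mean effects and mock roots, most other splits mixed the compared groups. The real effect then entered their residual spread and lowered their counts, so these splits cannot exclude chance. For the difference, the mean of each cultivar and day was removed before arrays were exchanged. The median residual SD was 0.366 for the real split and 0.340 for other splits. These medians cover all probe sets tested and not the 144 called. In the 144, a real difference would enter the residual spread of mixed splits as well. The splits of the difference therefore cannot exclude chance either. The real counts and the highest of the other splits were 3743 and 1609 for the mean effect in Nipponbare, 7097 and 6007 in IAC165, 144 and 20 for their difference, and 7614 and 3827 for mock roots. The real count for the difference was 13 without the intensity trend and 14 with centring on the median of all probe sets, and chance was not tested for these.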
